A study of Homo sapiens with 12 samples.

How the data were processed

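RNA from 4 human bladder cancer cell lines, Vmcub1, T24, J82 and HT, was measured on single-colour Illumina bead arrays with biotin-labelled cRNA, 3 arrays a line and 12 arrays in all. HT is called HT1376 in the series' design text. Per the labels, total RNA was extracted with Trizol and cleaned on columns with DNase, and Vmcub1 and T24 are classed as sensitive to hedgehog and J82 and HT as insensitive. The labels do not say how sensitivity was tested, nor whether the 3 replicates of a line were separate cultures, so p-values measure the spread between these samples, which may be technical.

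The authors deposited a raw table that gives each of 47228 probes a signal intensity and a detection score on every array, per the file headers. The detection score is headed as a p-value, but bright probes score near 1, so it was used as 1 minus the p-value. The authors also deposited a table of log2 values. Its scale, centring and direction are not stated, and they were worked out from the raw table: its values equal the log2 raw signal after quantile normalization, with no background correction, minus each probe's median over the 12 arrays, to within 0.00093. Its columns' own medians are near 0, and no part of its scale stays unknown. The software behind these files is not given in the sources used here.

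The raw intensities were background corrected, quantile normalized and log2 transformed with neqc in limma 3.58.1 under R 4.3.3, with an offset of 16 and the negative-control mean and SD inferred from the detection p-values. A probe was kept when its detection p was under 0.05 on all 3 arrays of at least 1 line, which left 22946 probes. Gene symbols came from the platform annotation: 30112 probes had 1 symbol, 8 had several and were not named, and 17108 had none listed. Identifiers of 30073 probes were found in a RefSeq gene table of assembly GRCh38.p14, and no symbol had to be changed. That table was used only for names and for the order of neighbouring genes. The kept probe with the highest mean stood for each gene, which gave 12520 genes, 3698 of them with more than 1 kept probe. Probes of one gene were called in opposite directions for 4 to 6 genes in each comparison of lines. Of the genes with several probes and any call, 544 of 1029 had a probe that was not called for T24 and J82, and 660 of 1300 for J82 and HT.

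Array brightness may limit precision. Median raw signal lay between 52.4 and 87.1, with HT replicate 2 the dimmest, and 42.5% to 46.5% of probes were detected on each array. The median SD between arrays was 0.102 in HT and 0.0971 to 0.101 in the other lines, so no loss of precision showed there. The number of arrays also limits precision. A gene not detected on any array of the dimmer line has only a bound there. Its fold is then given as "at least", from the brighter line's mean over the dimmer line's mean of, per array, the lowest detected signal or the probe's own value if higher.

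A linear model with 4 line means was fitted to the 12 arrays with lmFit and eBayes in limma, and all 6 pairs of lines were compared. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1. A gene counts as shared by the classes when called in the same direction in all 4 comparisons of a sensitive with an insensitive line, and as specific to a line when called in the same direction against each of the other 3. Because the cell line is the replicate of a class, the classes were also compared with limma on the 4 line means, 2 against 2, which leaves 2 residual degrees of freedom. An exact permutation of the lines could not give a p under 0.333.

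Before the data were examined, 41 gene lists, the design and the rule for named genes were fixed. The lists were tested with camera at a preset correlation of 0.01, and with fry, in the 6 pairs and between classes, 287 tests in one adjustment. Their overlap with shared and line-specific genes was tested with Fisher's exact test, two-sided, in 492 tests chosen after the data were seen. The shared genes tested were those of the classes and those of T24 and J82 against Vmcub1 and HT. Genes shared by T24 and HT against Vmcub1 and J82 were not tested this way. Fisher's test takes the members of a list as independent, so its p-values are too small where members vary together. The named genes are the 12 shared genes highest and the 12 lowest in the sensitive lines by their smallest difference, every measured hedgehog pathway component, the 3 largest called differences each way for a pair, the 5 genes each way specific to a line, and up to 4 called members each way of a list. Y-linked genes, XIST, TSIX and placeholder symbols (those opening with LOC, HS., KIAA, FLJ, MGC or FAM, and open reading frames named by chromosome) were passed over.

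The alternatives were no background correction, cyclic loess, the authors' log2 table, no detection filter or a stricter one (p under 0.01 on at least 6 arrays), every probe, trend and robust moderation, a block for the replicate number, no fold threshold, only the 6 arrays of a pair, each array left out, other class models, and an estimated correlation. Counting near-identical GAGE genes once was added after seeing the data.

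The steps were tested on simulated data with the real means and spreads of 12520 genes, 200 of them changed. In T24 against J82, 100% of genes changed by 1.5 and 100% of those changed by 3 on the log2 scale were recovered, with 0 unchanged genes called. In the class comparison on line means, 31% of genes changed by 3 and 89% of those changed by 6 were recovered, with 12 unchanged genes called. A search for runs of neighbouring genes took the median of 15 genes in chromosomal order and compared it with 2000 permuted orders, multiplying the share by the 4 lines. After the data were seen, it replaced a comparison with the highest of 30, then of 100, permuted orders. The highest of 100 missed a planted run, and the present form recovered it in 13 windows with 0 windows elsewhere.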

Results

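Gene expression was measured in 4 bladder cancer cell lines, on 3 arrays each. Vmcub1 and T24 are labelled as sensitive to hedgehog, a secreted developmental signal, and J82 and HT as insensitive. The series' design text asks which genes differ between the lines and which pathways they belong to, and the labels add the contrast between the classes. Of 47228 probes, those that passed the detection filter stood for 12520 genes. Each array detected 42.54% to 46.54% of the probes, and the number of arrays limits the precision. Values are normalized log2 signals, given as mean ± SD over 3 arrays, and adjusted p-values are from limma.

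The lines differed far more than their replicates. Arrays of one line correlated across genes at 0.9958 to 0.9966, and arrays of different lines at 0.8169 to 0.888. The median SD between arrays of one line was 0.1 on the log2 scale. Component 1 carried 43.4% of the variance and set HT apart from T24 and J82. Component 2 carried 30.6% and set Vmcub1 apart, and component 3, with 23.9%, parted T24 from J82. Clustering of the 12 arrays returned the 4 lines. T24 joined J82 at a distance of 0.113, Vmcub1 joined that pair at 0.144, and HT joined last at 0.174, so the labelled classes did not form branches.

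**Figure D1:**
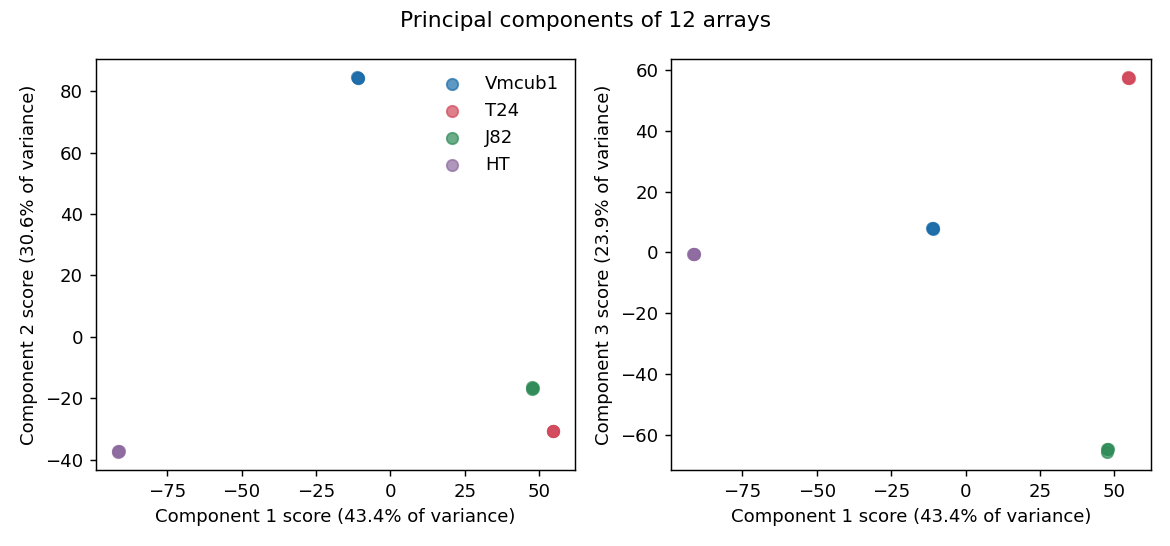
Scores of the 12 arrays on components 1 and 2 (left) and 1 and 3 (right), coloured by line, with the percent of variance on each axis. The 3 arrays of each line overlap, and T24 and J82 lie close on component 1, which carries 43.4% of the variance.

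Of the genes that separated the labelled classes, MT1E, a metallothionein, stood at 13.37 ± 0.19 in Vmcub1 and 13.77 ± 0.15 in T24, against 6.79 ± 0.14 in J82 and 6.24 ± 0.18 in HT. DMKN, an epidermal secreted protein, was at least 58.3-fold higher in either sensitive line than in either insensitive one. HSPA1A, an inducible heat shock protein, was 26.0-fold higher at the least separated pair of lines, and TPM2, a tropomyosin, was 8.61-fold higher. CD163L1, HOXB2, MAP1LC3A, S100A2, SLC6A10P, SIRPA, RAB34 and ADGRL2 completed the 12 genes highest in the sensitive lines. MT1E, HSPA1A, CD163L1 and SLC6A10P have near relatives whose transcripts the probes may also bind.

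Lower in both sensitive lines were MOXD1, a monooxygenase-like protein, FSTL1, a secreted glycoprotein, and TIMP3, an inhibitor of matrix metalloproteinases. None of these was detected in Vmcub1 or T24. MOXD1 was at least 17.7-fold, FSTL1 at least 12.4-fold and TIMP3 at least 11.5-fold higher in the insensitive lines. SFRP1, a secreted WNT antagonist that also stands in the fixed list of hedgehog response targets, was 9.18 ± 0.14 in J82 and 8.36 ± 0.10 in HT, against 4.67 ± 0.12 in Vmcub1 and 4.74 ± 0.32 in T24, where it was detected on 1 array. KRT8, a keratin of simple epithelia, was 12.61 ± 0.08 in J82 and 13.49 ± 0.17 in HT, against 8.68 ± 0.03 in Vmcub1 and 5.34 ± 0.09 in T24. MLPH, L1CAM, PRUNE2, VGLL3, BEX4, EPAS1 and CRISPLD2 were the others.

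In all, 83 genes were higher and 199 lower in the sensitive lines in all 4 comparisons, 282 together. With no fold threshold the balance turned, with 964 higher and 800 lower. The same count for the other ways to pair the lines was 574 for T24 and J82 against Vmcub1 and HT, and 300 for T24 and HT against Vmcub1 and J82. The labelled classes shared the fewest genes of the 3 pairings. Simulated lines without any difference shared 0 genes in each pairing. Independent lists of calls would share 5.42 for the classes, and 6.74 and 5.36 for the other pairings. Neither value tests the classes, because real lines differ and the 4 comparisons reuse the same lines. With the line as the replicate, limma called 0 genes between the classes, the lowest adjusted p being 0.489. At an unadjusted p under 0.05 there were 435 genes, where chance gives 626. With the line as a random block over the 12 arrays limma called 133, but that model draws its degrees of freedom from the arrays. The lists for luminal urothelial markers, cholesterol synthesis, matrix proteases, cancer-testis antigens and region 6p22 were lower in the sensitive class with camera (adjusted p = 0.0182, 0.0333, 0.0185, 0.00878 and 0.0018). None of these camera calls held: adjusted p = 0.476, 0.551, 0.332, 0.752 and 0.3 with an estimated correlation. Among the genes lower in both sensitive lines, luminal markers were overrepresented, with 4 of 22 where 0.35 would be by chance (Fisher's exact test, adjusted p = 0.0162). The same markers were overrepresented among genes specifically higher in Vmcub1 (5 of 22, adjusted p = 0.0337), a sensitive line, and in HT (6 of 22, adjusted p = 0.0367), lower in T24 (5 of 22, adjusted p = 0.0136), and lower in T24 and J82 than in both other lines (4 of 22, adjusted p = 0.0395). Among the genes lower in both sensitive lines, matrix proteases (3 of 21, adjusted p = 0.0806) and region 6p22 (2 of 7, adjusted p = 0.0913) did not pass. Matrix proteases were overrepresented among genes specifically lower in Vmcub1 (5 of 21, adjusted p = 0.00557) and higher in J82 (5 of 21, adjusted p = 0.0395). The cholesterol and cancer-testis lists had 0 genes among those lower in both sensitive lines.

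**Figure D2:**
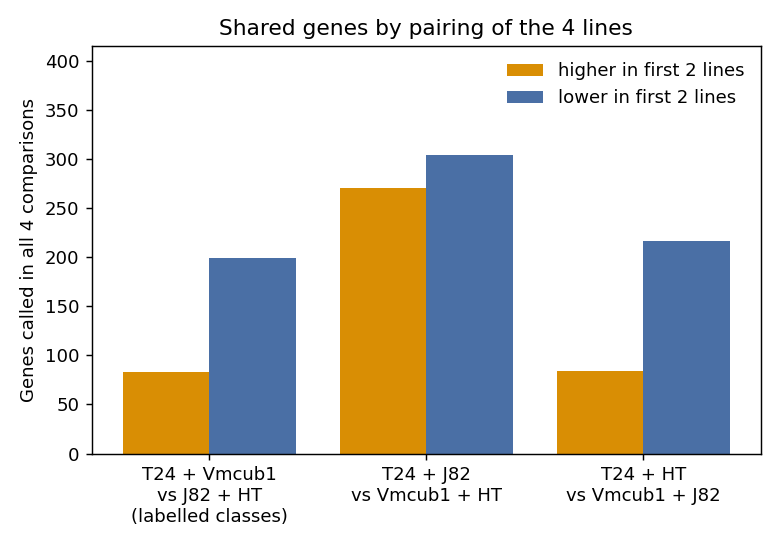
Number of genes called in the same direction in all 4 comparisons between 2 lines and the other 2, for the 3 ways to pair 4 lines; bars start at 0 and give genes higher or lower in the first 2 lines. The labelled classes share 282 genes and T24 with J82 against Vmcub1 with HT 574.

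Hedgehog pathway components did not follow the classes as a group. Of 24 listed components 22 had a named probe and 13 passed the detection filter. SMO, the signal transducer of the pathway, was detected only in T24, at 7.21 ± 0.10, where it was called against each other line. GLI2, a transcription factor of the pathway, was 5.83 ± 0.11 in T24 and not detected in Vmcub1, J82 or HT. PTCH1, the hedgehog receptor, was 5.33 ± 0.26 in T24 and not detected on any array of the others. T24 was only 0.56 to 0.88 higher on the log2 scale, so PTCH1 was called in no comparison. GAS1, a hedgehog co-receptor, ran the other way: it was 9.44 ± 0.21 in HT and 6.41 ± 0.11 in J82, against 5.18 ± 0.11 in Vmcub1 and 4.99 ± 0.27 in T24, where 1 array detected it. Of the 13 measured components, GAS1 alone was shared by the classes, with a smallest difference of 1.22. The ligands SHH and IHH, the target and effector GLI1, and HHIP, BOC, SCUBE2, EVC and EVC2 were detected on 0 of 12 arrays. DHH was detected on 6 arrays but on all 3 of no line. SUFU, STK36, KIF7, DISP1 and IFT88 were detected on all 12. GLI3, another transcription factor of the pathway, was 6.80 ± 0.13 in HT, 6.10 ± 0.34 in T24, 5.26 ± 0.19 in J82 and 4.91 ± 0.22 in Vmcub1. DISP2 was 6.83 ± 0.28 in HT and 4.93 ± 0.26 in Vmcub1, and HHAT was 5.36 to 5.56 in the other lines and not detected in Vmcub1. CDON lay between 4.87 and 5.43. Between the classes the components had a median log2 difference of -0.04 (camera adjusted p = 0.58), and the hedgehog response targets one of 0.31 (adjusted p = 0.921). Of the 13 measured targets, 4 were specifically higher in Vmcub1, where 0.497 would be by chance (Fisher's exact test, adjusted p = 0.0337). T24, the other sensitive line, had 0 specifically higher and 1 lower, and 0 were higher and 1 lower in both sensitive lines.

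**Figure D3:**
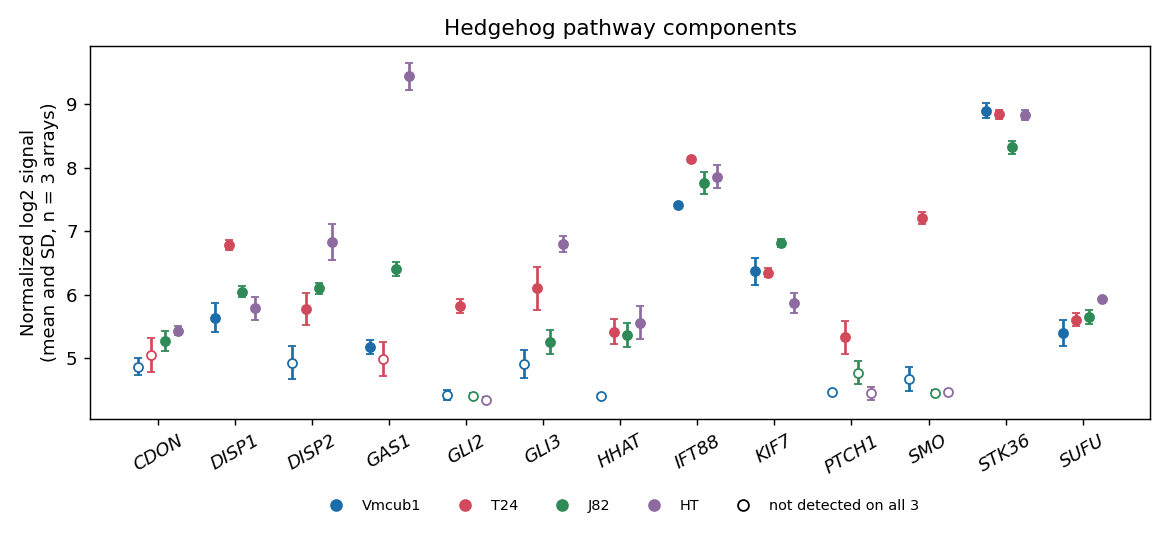
Normalized log2 signal of the 13 measured hedgehog pathway components in each line; points are means of 3 arrays, bars are SD, and open points mark lines where the gene was not detected on all 3 arrays. SMO, GLI2 and PTCH1 are filled only for T24, and GAS1 is highest in HT at 9.44.

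Epithelial adhesion genes were low in T24 and J82 and high in Vmcub1 and HT. Of 26 measured members, 24 were lower in J82 than in HT and 21 lower in T24 than in HT, with none higher. Against Vmcub1, 22 were lower in J82, and 20 were lower and 2 higher in T24. CDH1, or E-cadherin, was at least 63.7-fold lower in J82 and at least 60.7-fold lower in T24 than in HT. EPCAM, an epithelial adhesion molecule, was at least 121-fold lower in T24 than in HT, and JUP, or plakoglobin, at least 125-fold lower in J82. The list was called in these 4 comparisons (camera adjusted p = 6.17e-12, 6.68e-10, 1.73e-10 and 2.89e-07). All 4 stayed under 0.05 in camera with an estimated correlation, with adjusted p = 0.00614, 0.00614, 0.00614 and 0.0101. For every pair of lines, here and below, that correlation is estimated from deviations between arrays of one line. It does not cover how members vary together between lines, so these values leave that dependence unmeasured. Adjusted over the list alone, the counts were the same. Of the 26 genes, 19 were lower in T24 and J82 than in both other lines, where 0.631 would be by chance (Fisher's exact test, adjusted p = 3.31e-23), and 4 were specifically lower in J82 (adjusted p = 0.0162). Fisher's test ignores correlation between members, so here and for the other lists its p-values do not measure the strength of evidence.

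Basal and squamous genes divided the lines in the same way. Of 26 measured, 22 were lower in T24 and 20 in J82 than in HT, and 22 were higher in Vmcub1 than in T24 and 21 higher than in J82. KRT14 and KRT5, a pair of basal keratins, stood at least 264-fold and at least 225-fold higher in Vmcub1 than in J82. SPRR3, a cornified envelope protein, was at least 122-fold lower in T24 than in HT. CD44, an adhesion receptor on the same list, went the other way and was 13.64 in J82, 13.07 in T24, 11.73 in Vmcub1 and 11.10 in HT. The 4 calls stayed under 0.05 in camera with an estimated correlation, each with adjusted p = 0.0312. Of the 26 genes, 17 were lower in T24 and J82 than in both other lines and 9 specifically higher in Vmcub1 (Fisher's exact test, adjusted p = 1.43e-19 and 2.8e-05). Vmcub1 and HT differed within the list: KRT5 and KRT6C were higher in Vmcub1 by 6.90 and 6.87, and S100A7 was at least 96.8-fold lower. KRT6C has near-identical relatives.

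Mesenchymal genes mirrored this in part, and more in J82 than in T24. Of 24 measured, 5 were higher in T24 and J82 than in both other lines, where 0.518 would be by chance, and 0 were lower (Fisher's exact test, adjusted p = 0.00746). J82 had 13 higher and 3 lower than HT (camera adjusted p = 0.0029, and adjusted p = 0.0683 with an estimated correlation), and Vmcub1 had 12 lower and 4 higher than J82 (adjusted p = 0.011, and adjusted p = 0.102 with an estimated correlation). Against HT, T24 had 7 higher and 5 lower, a median log2 difference of 0.01 (adjusted p = 0.788). J82 had 6 of 24 specifically higher (Fisher's exact test, adjusted p = 0.0162) and T24 had 1. T24 and J82 also differed from each other, with 13 of 24 members lower in T24 and 2 higher (camera adjusted p = 4.18e-04, and adjusted p = 0.0339 with an estimated correlation). COL5A1, a collagen, was at least 34.7-fold lower in T24 and LOX, a collagen crosslinking enzyme, at least 12.6-fold lower, while VIM, or vimentin, was 2.34 higher on the log2 scale. CDH2, or N-cadherin, was 13.42 ± 0.04 in J82, 11.49 ± 0.08 in T24 and 9.36 ± 0.08 in Vmcub1, and was not detected in HT. S100A4, a calcium-binding protein on the same list, was highest in HT, at 15.09 against 6.96 in J82.

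**Figure D4:**
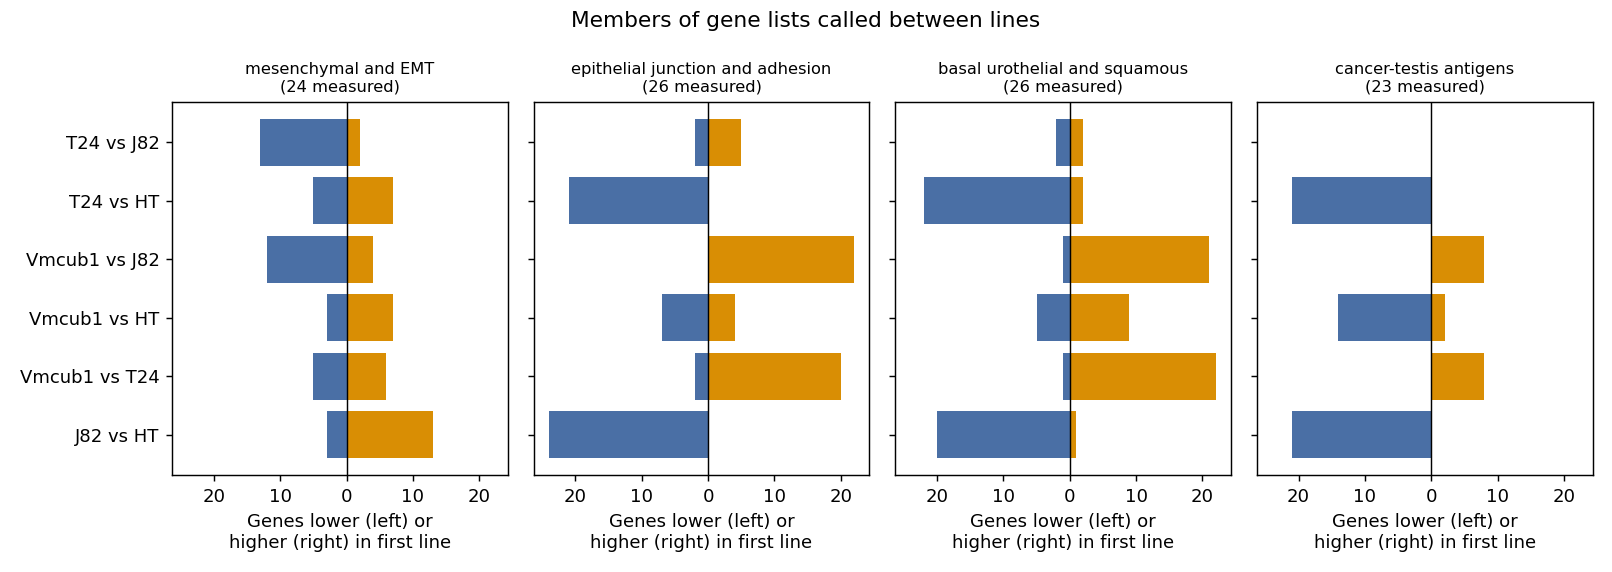
Members of 4 gene lists called lower (bars to the left) or higher (bars to the right) in the first line of each pair; the horizontal axis counts genes. Epithelial and basal members are low in T24 and J82, for example 24 of 26 epithelial genes in J82 against HT.

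HT stood out by cancer-testis antigens, genes normally expressed in germ cells. Of 23 measured members, 21 were lower in T24 and 21 in J82 than in HT, with none higher, and 14 were lower and 2 higher in Vmcub1. The calls stayed under 0.05 in camera with an estimated correlation, with adjusted p = 0.0101, 0.0101 and 0.0312. GAGE4 was at least 1440-fold higher in HT than in the other lines, and GAGE12B, GAGE12G, GAGE12F and GAGE12J at least 1090-fold, 1270-fold, 1240-fold and 1200-fold. These copies are nearly identical, so their probes may give a single family signal. The list tests here still counted each listed GAGE gene separately, which can inflate them. They were not rerun with the GAGE genes counted once. SSX2 and MAGEA8 were at least 147-fold and 127-fold lower in T24. Of the 23 genes, 14 were specifically higher in HT, where 1.37 would be by chance (Fisher's exact test, adjusted p = 4.94e-10). Some members were high in Vmcub1 too: 7 of 23 were lower in T24 and J82 than in both Vmcub1 and HT (Fisher's exact test, adjusted p = 6.69e-05). Vmcub1 had 8 higher and 0 lower than J82, and 8 higher and 0 lower than T24 (camera adjusted p = 0.0284 and 0.0195, and adjusted p = 0.213 and 0.198 with an estimated correlation). MAGEC1 and MAGEA10 were higher in Vmcub1 than in HT, MAGEC1 at least 12.9-fold. HT had 744 genes specifically higher and 363 lower, or 406 and 363 with the stricter detection filter. MSN, or moesin, which links actin to the membrane, was 6.16 ± 0.20 in HT against 11.47 to 12.05 in the others. NECTIN3, CDH2, RFTN1 and TUBB3 were the next lowest.

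Vmcub1 had 479 genes specifically higher and 286 lower, or 306 and 286 with the stricter detection filter. FST, or follistatin, was at least 266-fold higher than in any other line, ALDH3A1, an aldehyde dehydrogenase, at least 194-fold, and CALML3, a calmodulin-like protein of epithelia, at least 144-fold. Inflammatory cytokines were overrepresented, with 9 of 21 measured specifically higher where 0.803 would be by chance (Fisher's exact test, adjusted p = 3.91e-06). IL1A, a proinflammatory cytokine, was at least 75.7-fold higher than in T24, and LCN2 at least 32.4-fold. As a list the cytokines were called against T24 (12 of 21 higher, camera adjusted p = 0.00188) and HT (10 higher, adjusted p = 0.00301), but adjusted p = 0.0618 and 0.0707 with an estimated correlation. Aldehyde dehydrogenase and xenobiotic genes gave 6 of 20 specifically higher and hypoxia response genes 5 of 23 (Fisher's exact test, adjusted p = 0.00524 and 0.0375). PLAC8, QPRT, CEP15, EVA1A and PEG10 were not detected in Vmcub1 and were at least 43.0-fold, 32.4-fold, 34.2-fold, 28.5-fold and 27.8-fold lower.

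T24 had 388 genes specifically higher and 345 lower, a balance that turned with cyclic loess (327 and 402) and with the stricter detection filter (261 and 345). TM4SF18, a membrane protein, was at least 69.8-fold higher than in the other lines, and LAT2 and WSCD1 at least 20.5-fold each. ATP8B2 followed, and ZFP30, a zinc finger gene, stood at 11.52 ± 0.11. Lowest were ANXA3, an annexin, at least 60.7-fold, LGALS3, or galectin-3, at least 44.1-fold, and CD24, a surface glycoprotein, at least 29.9-fold, with KRT7 and ARHGDIB. Class I antigen presentation genes were lower in T24 than in J82 in 8 of 15 (camera adjusted p = 0.00241), with adjusted p = 0.149 with an estimated correlation. Among genes specifically lower in T24 they were 4 of 15, where 0.413 would be by chance (Fisher's exact test, adjusted p = 0.0199). Of these genes HLA-B was 5.54 in T24 and 11.67 in J82. Probes for HLA genes can bind allelic variants unequally.

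J82 had 545 genes specifically higher and 178 lower. The counts were 331 and 178 with the stricter detection filter and 377 and 84 without background correction. DIO2, which activates thyroid hormone, was at least 128-fold higher than in the other lines. OXTR, the oxytocin receptor, was 13.72 ± 0.12 against 6.51 to 7.22. BAMBI, a TGF-beta pseudoreceptor, and LRIG1, a negative regulator of receptor tyrosine kinases, were at least 55.0-fold and 38.5-fold higher, and TENM3 followed. ALDH7A1, TEAD2, CPNE8 and OAT were not detected in J82, and DKK3 was 4.76 ± 0.26. Cholesterol and fatty acid synthesis genes were specifically higher in 6 of 24 (Fisher's exact test, adjusted p = 0.0162). In T24 against J82, 12 were lower and 1 higher (camera adjusted p = 4.69e-04, but adjusted p = 0.213 with an estimated correlation), among them SQLE at 10.61 and 12.75.

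Between pairs of lines, T24 and J82 differed by the fewest genes, 2630, and J82 and HT by the most, 3448. The others were 3010 for Vmcub1 and T24, 3049 for Vmcub1 and J82, 3060 for Vmcub1 and HT, and 3364 for T24 and HT. TGM2, a transglutaminase, was 132-fold higher in T24 than in J82, and TGFBI, a matrix protein, 235-fold lower. LCP1 and OLR1 were at least 286-fold and 131-fold lower in T24. KRT19 was at least 696-fold higher in Vmcub1 than in T24, and UBASH3B and SHISA2 at least 121-fold and 103-fold lower. VIM was 129-fold higher in T24 than in HT. BNIP3, a mitophagy receptor, was 13.21 in J82 against 4.97 in Vmcub1, where 2 of 3 arrays detected it. SRGN was 12.06 in J82 and 4.79 in Vmcub1, where 1 array detected it, and BCAT1 was at least 131-fold higher in J82 than in HT. Without background correction, the T24 and J82 count was 1718 and the Vmcub1 and J82 count 2003, and the genes shared by the classes were 160.

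Of the 41 lists, 21 were called in at least 1 pair of lines and 20 in no comparison. In all, 48 of 287 tests were called, 12 of them with an estimated correlation. Those 12 lay in the epithelial, basal, mesenchymal and cancer-testis lists. Integrins and laminins were lower in T24 and J82 than in both other lines in 4 of 20 (Fisher's exact test, adjusted p = 0.0337). Markers of immune and endothelial cells were called in no pair. Markers of smooth muscle and fibroblasts were lower in Vmcub1 than in J82 in 5 of 8 (camera adjusted p = 0.0245, and adjusted p = 0.172 with an estimated correlation).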

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

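All settings here were chosen before the data were examined, except the single count of GAGE genes. Without background correction, counts moved to 1718 genes for T24 and J82, 2003 for Vmcub1 and J82, 160 shared by the classes, and 455, 445 and 461 specific to Vmcub1, T24 and J82, and the authors' log2 table gave the same counts. Every gene called there in the 6 pairs was also called in the same direction with correction. The correction widens differences of dim genes by its construction. The other pairings of the lines moved to 355 (T24 and J82 against Vmcub1 and HT) and 167 (T24 and HT against Vmcub1 and J82). With every probe, 22946 in place of 12520 genes, pair counts were 4274 (T24 and J82), 5488 (T24 and HT), 4837 (Vmcub1 and J82), 4935 (Vmcub1 and HT), 4893 (Vmcub1 and T24) and 5520 (J82 and HT), with 426 shared by the classes, 880 and 446 for the other pairings, and 1182, 1200, 1148 and 1784 specific to Vmcub1, T24, J82 and HT. With no fold threshold, in the same order, they were 8604, 9014, 8658, 8879, 8777 and 9083, then 1764, 2403 and 1920, then 3326, 3478, 3207 and 3954. Treating the line as a random block called 133 genes between the classes, and treating the 12 arrays as replicates of a class called 2418. The 2418 takes arrays of one line as independent. The random block uses a common within-line correlation for all genes and draws its degrees of freedom from the arrays. The line alone is therefore not its replicate, and the cause of the 133 was not tested further. The list tests called fell from 48 to 12 with an estimated correlation and rose to 227 with fry, which does not compare a list with other genes.

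Leaving out each array in turn gave 2630 to 2661 (T24 and J82), 3360 to 3387 (T24 and HT), 3016 to 3055 (Vmcub1 and J82), 3050 to 3075 (Vmcub1 and HT), 3003 to 3022 (Vmcub1 and T24), 3428 to 3476 (J82 and HT), 279 to 289 shared by the classes, 561 to 579 and 294 to 302 for the other pairings, 754 to 778, 728 to 737, 715 to 736 and 1101 to 1128 specific to Vmcub1, T24, J82 and HT, and 0 to 0 on line means. The range includes HT replicate 2, the dimmest array. Cyclic loess, both detection filters, trend and robust moderation and counting GAGE genes once left the pair, shared and specific totals within 1.5 times. So did the 6 arrays of a pair for the pair counts. Trend and robust moderation, the 6 arrays of a pair and leaving out an array of an uninvolved line cannot change a pair's log2 differences. They can act on its calls only through the adjusted p, and the T24 and J82 count stayed at 2630 under each. These settings test the pair counts only weakly. The stricter filter moved specifically higher genes further, to 306 in Vmcub1, 331 in J82 and 406 in HT, since a gene detected in 1 line alone cannot pass it. The direction with more genes turned in some settings. With no fold threshold this held for T24 and J82 (4657 higher, 3947 lower), T24 and HT (4904, 4110), Vmcub1 and J82 (4487, 4171), Vmcub1 and HT (4610, 4269), Vmcub1 and T24 (4165, 4612), the classes (964, 800) and T24 with J82 against the others (1254, 1149). With the stricter filter it held for T24 and HT (1428, 1396), Vmcub1 and HT (1277, 1204) and T24 alone (261, 345), and with cyclic loess for T24 alone (327, 402). The labelled classes shared the fewest genes of the 3 pairings without background correction, with every probe and with no fold threshold too. Deviations of same-numbered arrays correlated at -0.035 to 0.033, so no shared effect of the replicate number showed. This cannot tell whether same-numbered samples were handled together. A replicate block kept every pair count (2630 for T24 and J82). All lines share replicate numbers, so the block cannot change a log2 difference, and these counts do not test pairing. Of 1148 differences of named genes, 173 fell below the threshold without background correction, 33 with cyclic loess and up to 15 without 1 array. The stricter filter left 959 to compare, and 0 reversed in any setting. No slide is named here, so no slide block was run.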

Other observations

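The gene families, imprinted genes and runs of neighbouring genes were looked at only after the data were seen, as were all tests in this part except the splits of arrays for pairs of lines and the regroupings for single lines, whose division by whether a line stayed together also came after. All 8 measured pregnancy-specific glycoprotein (PSG) genes, normally placental, were specifically higher in J82, where 545 of all 12520 genes were. Their median was 4.14 on the log2 scale over the median of the other lines (2.84 without background correction, 4.12 with cyclic loess). PSG genes are similar in sequence, and whether their probes give 8 separate signals was not tested. Some zinc finger genes were specifically higher in T24: 12 of 29 on chromosome 7, 41 of 190 on chromosome 19 and 15 of 194 elsewhere, where 388 of all 12520 genes were. Their median differences were 0.99, 0.50 and 0.33, and 0.70, 0.36 and 0.21 without background correction and 0.86, 0.40 and 0.20 with cyclic loess. No test of these families against other genes was run.

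Of the imprinted genes looked for, 8 were measured, and they were not tested as a group. Between 21% and 27.5% of all genes differed in a pair of lines. H19 was 14.19 ± 0.03 in HT and 4.38 to 5.06 in the others, and IGF2 was detected only in HT, at 5.99 ± 0.02. NDN was 9.86 ± 0.10 in HT, 5.15 ± 0.13 in Vmcub1 and not detected in T24 or J82. PLAGL1 was detected only in Vmcub1, at 8.93 ± 0.05, and PEG10 in every line but Vmcub1. MEST was 7.19 ± 0.09 in J82 and detected on 1 array of HT and none of the other lines. SNRPN and PHLDA2 were detected on all 12 arrays. SNRPN was 10.18 ± 0.03 in T24 and 6.04 to 7.96 in the others. PHLDA2 was 8.17 ± 0.03 in HT and 6.26 to 7.33 in the others. It ends a passing run of 16 neighbouring genes on chromosome 11, from CTSD, that was higher in HT. That run had a median of 1.65 and a share of 0.04 after allowing for the 4 lines. Imprinted genes within it may not be separate observations.

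Of the runs of neighbouring genes, 18 passed in the 4 lines, 3 in Vmcub1 and 5 in each of the others. The most extreme window, with a median of 9.95, lay in HT on chromosome X between WDR45 and MAGED4B, a run with 10 GAGE genes. The median over that whole run was 1.48. In J82 a run on chromosome 19 from ERF to PLAUR (window 2.61, whole run 0.36) held the 8 PSG genes. T24 had a run on chromosome 7 from NIPSNAP2 to VKORC1L1 (window 1.70, whole run 1.14), with 12 zinc finger genes of 24. Its runs on chromosome 19 (windows 1.62, 1.87 and 2.07, whole runs 1.42, 1.32 and 1.12) held 21 of 28, 25 of 36 and 16 of 24. Runs with S100 and SPRR genes on chromosome 1 were higher in Vmcub1 (window 2.52, whole run 1.15) and HT (2.58, 1.43). They were lower in T24 (-2.21, -1.29) and J82 (-2.26, -2.26). Each of these had a share of 0.002 after allowing for the 4 lines, the smallest that the permutations can give, except 0.004 for the window of 1.62. Permuted orders scatter similar neighbouring genes, so these shares cannot tell a gene family from a shift of a whole region.

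Vmcub1 had a pair of passing runs on chromosome 11, from RCE1 to TMEM134 (window 1.34, share 0.038) and from KMT5B to PPFIA1 (window 1.31, share 0.044). The list for region 11q13, fixed before the data were examined, had 2 of 9 measured genes specifically higher in Vmcub1. By chance 0.344 would be, and the overlap did not pass (Fisher's exact test, adjusted p = 0.391). For the run from RCE1 to TMEM134, 18 of 2000 permuted gene orders held a window as extreme. That share lies narrowly under 0.05, by a rule that was changed after the data were seen, so it is weak evidence against a chance order. Its 13 genes detected on all 12 arrays had a median difference of 1.17 (quartiles 1.06 and 2.06). Keeping 1 gene per symbol root removed 0 of them and left 1.17, so copies of one gene family were not tested by it. Vmcub1 was the highest line in 92.3% of them, which follows from how the run was picked, and with no DNA measured a changed number of copies and joint regulation cannot be told apart.

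A run on chromosome 12, from MRPS35 to BICD1, was lower in HT, with a median difference of -1.58 over 11 genes detected on all arrays. It was picked when its most extreme window passed the highest of 30 permuted orders. It did not pass the highest of 100, and of 2000 orders 42 were as extreme, a share of 0.086 after allowing for the 4 lines, so a chance order of genes stays open. Keeping 1 gene per symbol root removed 0 genes and left -1.58, so it tests nothing about copies of one gene family. HT was the lowest line in 81.8% of the genes, which follows from how the run was picked and says nothing about DNA copies.

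For each pair of lines, 10 splits of the 6 arrays are too few for a share under 0.05. Only 1 split, the real one, gave as many genes each time, with 2630, 3364, 3049, 3060, 3010 and 3448 genes against a highest of 0 in the other splits. For the classes, all 3 pairings of the lines gave at least the 282 shared genes of the labelled one, the highest being 574, and 3 pairings are too few for a share under 0.05. For genes specific to a line, 100 groupings of the 12 arrays into sets of 3 were compared by their highest set. As many genes were found in 2 of them for Vmcub1 (765), 2 for HT (1107), 6 for T24 (733) and 7 for J82 (723), the real one included, and the highest other gave 1160. All others with as many genes kept the 3 arrays of a line together, as 6 of the 99 did, so these counts rank the lines against one another and do not test chance. The groupings that kept no line together gave 0 genes, which mixing lines in a set fixes in advance, so they do not test chance either.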
